A study of Mus musculus with 4 samples.

How the data were processed

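Deposited matrices of 3 slides were used, each holding whole-number counts of decoded transcripts per feature and segmented cell; the authors deposited these counts without normalization. All sections of a slide stood in 1 matrix, with 541 features: 297 gene features, 27 negative control probes, 41 negative control codewords, 175 unassigned codewords and 1 deprecated codeword. Decoding, quality threshold, segmentation settings and software versions, and the genome build behind the probes, are not given in the sources used here. Positions, sections and animals were not used, and slide 4 was not analysed here. The labels gave no slide a group, so each slide was analysed as a sample of its own and no test across slides was run.

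Lists of genes, cell type markers, the size rule, the rule for named genes and most of the alternatives below were set before the data were examined. The panel had no feature named Dmd, so the 17 features named for dystrophin isoforms, exon blocks and junctions were read in its place, which departs from the plan. Cells with fewer than 20 gene transcripts were left out (340, 286 and 1934 cells). A sample of 20000 cells per slide was clustered on 235 genes, with the 62 measured genes of the fixed lists held out. The 30 leading principal components, a graph of 15 nearest neighbours and the Leiden method at resolution 1 gave 44 clusters, and every cell was then assigned to its most likely cluster from multinomial profiles mixed with 2% of the mean profile. A cluster was named for a class with at least 2 of its markers among the 10 leading genes and at least 3 over 2-fold, which left 5 clusters unnamed and gave 9 classes. The rule for ties in naming, which settled 1 cluster, and the rule for region names were chosen after the clusters were seen. Fibroblast or meningeal-like cells were 1 cluster. Doublets were not called with a tool; instead the 10% of cells with the smallest margin between their best and next class were left out as an alternative.

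Counts were summed over the cells of a class in a slide and divided by the gene transcripts of the class, times 10000. A gene was called higher in a class when its ratio to all other named cells pooled was at least 2 in every slide, lower when it was at most 0.5 in every slide, with at least 50 counts in the class or in the rest. The same rule was applied to excitatory over inhibitory neuron-like cells. It is a rule of size and not a test, since cells are not replicates and give no p-values. Intervals are exact Poisson or exact binomial (Clopper-Pearson) at 95% and cover counting error only. The spread between slides was the highest over the lowest slide level, for genes with at least 200 counts in every slide.

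Named in the text were all dystrophin features of note and the dystrophin complex list; from each other list the 4 genes with the highest smallest-slide ratio in their leading class, among genes with at least 50 counts there and the same leading class in every slide; the 5 highest and 5 lowest genes of excitatory against inhibitory neurons, ranked by the slide ratio nearest to 1; and the 5 most uneven genes between slides, over all cells and within classes. Gfap, Cd44, Slc17a7, Igf2, Cldn5, Pdgfra, Crh, Npy2r and features named beyond this rule were chosen after their values were seen, as were the minimum of 20 counts for cluster ranges, the minimum of 10 counts per cell for exons 56 to 62, the ratios of exon blocks, and the bar for codewords, which was the highest negative control codeword in every slide.

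The steps were tested on simulated data. The size rule called 20 of 20 pairs simulated at 4-fold and 20 of 20 at 0.25-fold. It called 0 of 10 at 1.2-fold and 0 of 108 pairs from genes left unchanged in every class. The unchanged classes of changed genes were not counted, so false calls there were not tested. Counts were drawn without variation between slides, and no fold near the bounds of 2 and 0.5 was simulated. With equal rates in all slides, 0 of 297 genes differed over 1.5-fold. Class assignment was right for 100% of 7800 simulated cells drawn from pure cluster profiles, which does not test mixed cells.

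Alternatives changed 1 choice at a time, except for thinning: a minimum of 10 or 50 transcripts per cell, all genes used for clustering, resolution of 0.5 or 2 times the main value, another subsample, leaving out the 10% of cells of smallest margin or the top 1% by transcripts, thinning cells to 100 transcripts, mean counts per cell, a denominator of genes outside the lists, classes weighted equally, a size rule of 1.5 and its inverse, a minimum of 200 counts, and leaving out each slide. Thinning also left out the cells with fewer than 100 transcripts (24068, 24783 and 45548 cells), so it changed both the depth and the set of cells. Subtraction of the mean negative control probe was added after the data were seen. A share, median or cluster fold was taken as moved when it left the exact 95% binomial interval of its main value. A count was taken as moved when it changed more than 1.5-fold, and an uncalled single gene when its ratio crossed 1. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.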

Results

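In situ transcript counting (Xenium) was applied to hemi-coronal brain sections of mice, with a targeted probe panel read out in segmented cells. The study concerned exon skipping in the brain in Duchenne muscular dystrophy and used 12 mice, 3 in each of 4 groups, collected at 14 weeks of age (postnatal day 98). The groups were wildtype mice, mdx52 mice given PBS, mdx52 mice given a tricyclo-DNA antisense oligonucleotide, and mdx52 mice given an AAV vector carrying a U7 small nuclear RNA, both treatments being directed at exon 51 of Dmd. The mdx52 mouse lacks the Dmd exon between exons 51 and 53. Sections were 10 µm thick. The labels listed 4 slides and tied no slide or section to a group, so every value is given per slide, no study groups were compared, and slides were not treated as replicates. Slide 4 was not analysed here.

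The 3 slides held 329439, 317630 and 329560 segmented cells (slides 1, 2 and 3, the order used throughout) and 116872480, 110141363 and 124459019 gene transcripts. After cells with fewer than 20 gene transcripts were left out, 329099, 317344 and 327626 cells remained, with a median of 319, 312 and 332 transcripts. The panel had 297 gene features, 17 of them for dystrophin. These were 5 features for exon blocks, 3 for exon junctions and 9 for the isoforms Dp427c, Dp427m, Dp427p, Dp427p2, Dp260, Dp140, Dp116, Dp40 and the start shared by Dp71 and Dp40. The 27 negative control probes averaged 792, 729 and 829 counts per probe in all cells. Levels below are counts per 10000 gene transcripts, and intervals are exact 95% intervals that cover counting error only.

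Neurons made up the largest part of the named cells. Excitatory neuron-like cells were 28.5% to 30.8% of cells, lowest in slide 1 and highest in slide 3, and inhibitory neuron-like cells 13.3%, 14.1% and 12.5%. Oligodendrocyte-like cells were 15.9%, 14.97% and 15.2%, astrocyte-like cells 10.45%, 11.1% and 10.6%, and oligodendrocyte precursor-like cells 2.93%, 2.85% and 3.00%. Endothelial-like cells were 7.68%, 8.13% and 7.92%, and fibroblast or meningeal-like cells 3.45%, 2.69% and 3.07%, the last class falling to 1.68% in the median slide with finer clusters. Microglia or macrophage-like cells were 6.21% (6.12% to 6.29%, exact binomial) in slide 1 against 4.79% (4.71% to 4.86%) and 4.49% (4.42% to 4.56%) in slides 2 and 3. Ependymal or choroid plexus-like cells were 1.70%, 1.43% and 2.63%. Cells of 5 unnamed clusters were 9.80%, 9.90% and 9.77%. The fibroblast or meningeal-like class was a single cluster that also had 4 mural cell markers among its 10 leading genes.

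The question of which brain cells carry which dystrophin transcripts was addressed by comparing each class with all other named cells of the same slide. Dp427c, Dp427p, Dp427p2 and the block of exons 2 to 29, which only full-length dystrophin contains, were highest in excitatory neuron-like cells except that Dp427p2 was level with inhibitory neuron-like cells in slide 3. Dp40 and the start shared by Dp71 and Dp40 were highest in astrocyte-like cells. Dp427p, from the promoter first described in Purkinje cells, was 2.13 to 2.46-fold higher in excitatory neuron-like cells, at 4.35 (4.29 to 4.42), 4.18 (4.11 to 4.24) and 3.78 (3.73 to 3.84). Dp40, a short isoform that shares the Dp71 promoter, was 4.99 to 6.06-fold higher in astrocyte-like cells, at 12.4 (12.2 to 12.7), 14.3 (14.0 to 14.5) and 15.7 (15.4 to 15.9). In the same cells the start shared by Dp71 and Dp40 was 2.77 to 3.59-fold higher, at 7.55, 9.53 and 10.2. These levels lay below those of Dp40, although Dp40 has that start. Levels of different features therefore do not compare amounts of isoforms. Exon 79, the last exon, was 2.59 to 2.82-fold higher in astrocyte-like cells.

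Ependymal or choroid plexus-like cells differed from both neurons and astrocytes. Dp260, the isoform known from retina, was 4.25 to 5.33-fold higher there, at 2.50 (2.22 to 2.81), 2.25 (1.97 to 2.55) and 1.93 (1.76 to 2.12). The block of exons 30 to 44, which Dp260 shares with full-length dystrophin, was 2.28 to 3.25-fold higher, at 61.7, 53.4 and 42.0. Dp427c, Dp427m, Dp427p and Dp427p2 were all lower in these cells, with Dp427c at 1.81, 1.76 and 2.25 against 18.1, 20.4 and 17.1 in excitatory neuron-like cells. Dp140 was 2.13 to 3.30-fold higher in oligodendrocyte precursor-like cells, but on only 21, 22 and 26 counts, 0.878, 1.11 and 1.04 times the mean negative control probe of that class.

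Of the 19 measured members of the dystrophin complex list, 17 of them dystrophin features, 9 were higher and 14 lower in at least 1 class. The list also held Aqp4, the water channel of astrocyte endfeet, and Sntb1, a syntrophin that binds dystrophin. Aqp4 was 4.77 to 5.30-fold higher in astrocyte-like cells. Sntb1 was 10.6 to 12.8-fold higher in ependymal or choroid plexus-like cells and 2.51 to 2.97-fold higher in fibroblast or meningeal-like cells. Oligodendrocyte-like cells had 11 of these members lower, endothelial-like cells 9 and microglia or macrophage-like cells 8. Over the 17 dystrophin features and 9 classes, 7 pairs were higher and 32 lower. As mean counts per cell, 13 pairs were higher, and 14 members of the list in place of 9. Without slide 3, 11 pairs were higher. Several features led in a class without passing the rule of 2-fold in every slide. Dp427c, from the cortical promoter, was 1.69 to 2.16-fold in excitatory neuron-like cells, and Dp427m, from the muscle promoter, was 1.98 to 2.44-fold in fibroblast or meningeal-like cells. Dp427p2 was 1.81 to 2.33-fold in excitatory neuron-like cells, but did not lead there in slide 3, at 0.479 against 0.485 in inhibitory neuron-like cells. Dp116, the Schwann cell isoform, stayed at or under 0.194 in every class and slide, and over all cells had 1.82, 1.87 and 1.65 times the counts of the mean negative control probe, with 4, 4 and 6 probes above it. Dp427p lost its call with coarser clusters (1.91 in the median slide), the block of exons 30 to 44 in ependymal or choroid plexus-like cells lost it as mean counts per cell (1.84), and Dp140 lost it with classes weighted equally. With finer clusters, which gave mural cells a class of their own, Dp427m in fibroblast or meningeal-like cells fell to 0.407.

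**Figure D1:**
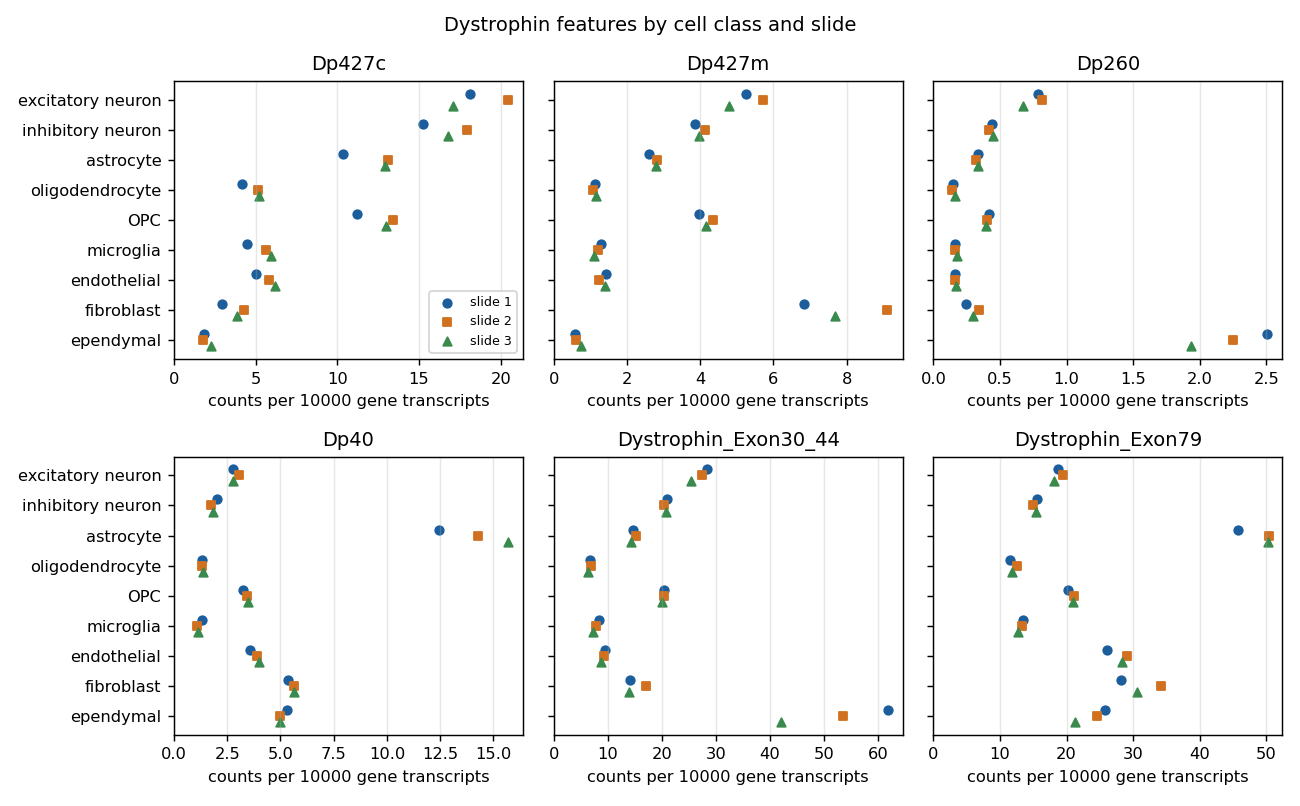
Levels of 6 dystrophin features in counts per 10000 gene transcripts for the named cell classes, with points for slides 1, 2 and 3. Dp40 is highest in astrocyte-like cells (12.4, 14.3 and 15.7) and Dp260 in ependymal or choroid plexus-like cells (2.50, 2.25 and 1.93).

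The junction features were taken, from their names alone, to read which exons are joined, since probe sequences were not known. Exon 51 joined to exon 53 is the product of the mdx52 allele, exon 50 joined to exon 53 is that allele with exon 51 skipped, and exon 50 joined to exon 51 occurs in wildtype and in unskipped mdx52 transcripts. Over all cells, the junction of exons 51 and 53 had 8100, 6332 and 7385 counts, the junction of exons 50 and 51 had 6453, 5589 and 6054, and the junction of exons 50 and 53 had 877, 1007 and 1016. Among counts of the junctions 50 to 53 and 51 to 53, the skipped form was 9.77% (9.16% to 10.4%), 13.7% (12.9% to 14.5%) and 12.1% (11.4% to 12.8%). In excitatory neuron-like cells this share was 9.50%, 10.2% and 12.1%, and in endothelial-like cells 31.9%, 38.4% and 29.5%. The endothelial shares rest on 74, 71 and 65 counts of the skipped form, against 55.4, 54.0 and 68.6 counts for the mean negative control probe of that class. In each slide 7 of the 27 negative control probes had more counts than the junction of exons 50 and 53. With the mean negative control probe subtracted, the share over all cells was 1.16%, 4.72% and 2.78%, and in excitatory neuron-like cells 4.75% (3.76% to 5.81%), 4.52% (3.37% to 5.74%) and 7.01% (5.85% to 8.21%). These intervals cover the counting error of the skipped form alone, with the other junction and the mean probe held fixed. In oligodendrocyte-like cells, with 51, 79 and 44 counts of the skipped form against 158, 139 and 141 for the mean probe, the same subtraction gave shares below 0, as it did in microglia or macrophage-like cells in every slide and in 5 other classes in some slides; these enter the share over all cells. Probes may differ in efficiency and the groups behind each slide are unknown, so the shares do not measure skipping in any treatment group.

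**Figure D2:**
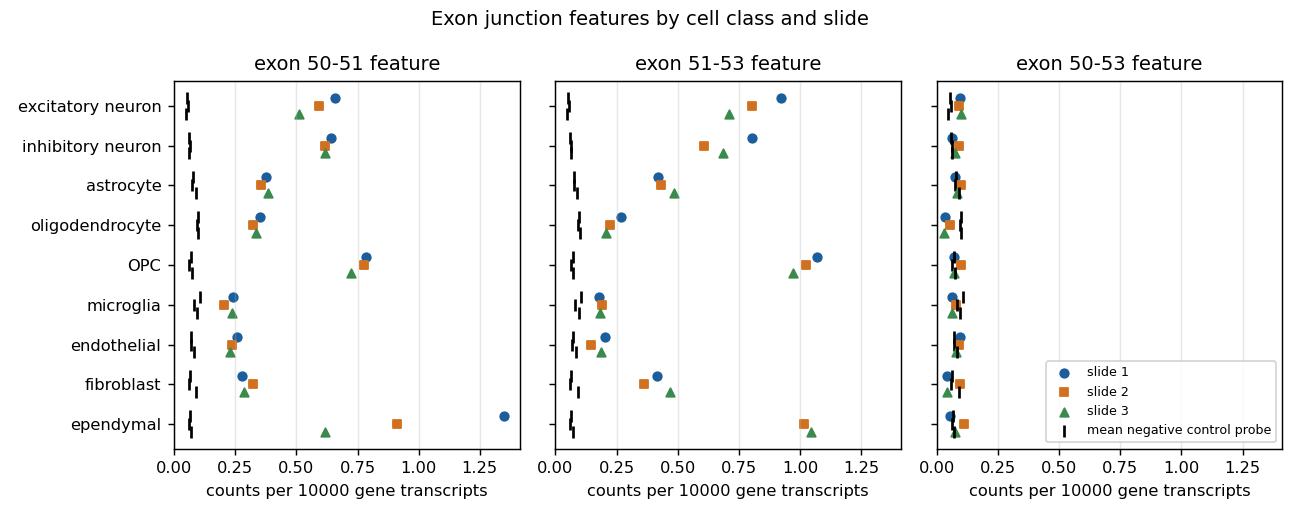
Levels of the dystrophin junction features in counts per 10000 gene transcripts by cell class, with points for slides 1, 2 and 3 and black ticks for the mean negative control probe of the class and slide. The junction of exons 50 and 53 lies above the mean negative control probe in excitatory neuron-like cells and below it in oligodendrocyte-like cells; over all cells the probe mean was 0.0677, 0.0662 and 0.0666 against 0.0750, 0.0914 and 0.0817 for the junction.

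Dystrophin levels differed widely among the 20 named neuronal clusters, and Dp427c and Dp40 went in opposite directions between the CA1 and dentate granule clusters of the hippocampus. Dp427c was highest in the CA1 cluster (led by Fibcd1, Gm2115 and Pou3f1), at 47.5, 52.4 and 45.9. It was lowest over the median of the slides in a thalamus cluster, at 6.08, 9.02 and 6.74, a difference of 5.80 to 7.82-fold, and was at 6.205, 8.07 and 6.86 in the dentate granule cluster. Dp260 was also highest in the CA1 cluster, at 2.27, 2.73 and 2.48, and 10.3 to 13.0-fold over its lowest cluster, at 0.220, 0.210 and 0.225. That lowest cluster, led by Cabp7, Orai2 and Fibcd1, also had Gm2115, Pou3f1 and the astrocyte marker Ntsr2 among its 10 leading genes, held 5116, 5974 and 7455 cells against 3038, 3987 and 4586 in the CA1 cluster, and met no region rule. Its Dp427c was at 7.55, 8.23 and 8.75 and its Dp40 at 6.09, 7.41 and 7.53, so the levels of the CA1 cluster did not hold for every cluster with these marker genes. Dp40 was highest in the dentate granule cluster (led by Prox1), at 9.56, 11.0 and 10.0, and lowest over the median of the slides in the CA1 cluster, at 1.62, 1.04 and 1.04, a difference of 5.92 to 10.6-fold. The start shared by Dp71 and Dp40 followed the same order, 7.62 to 10.7-fold from the dentate granule to the CA1 cluster. Exon 79 was highest in the cluster led by Cabp7, Orai2 and Fibcd1, at 29.7, 33.9 and 32.0, and lowest in a striatum cluster, at 9.74, 10.1 and 9.31. Ranges were taken over clusters with at least 20 counts of a feature in every slide, a minimum chosen after the values were seen. Clusters were named for a region from marker genes alone, without positions.

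**Figure D3:**
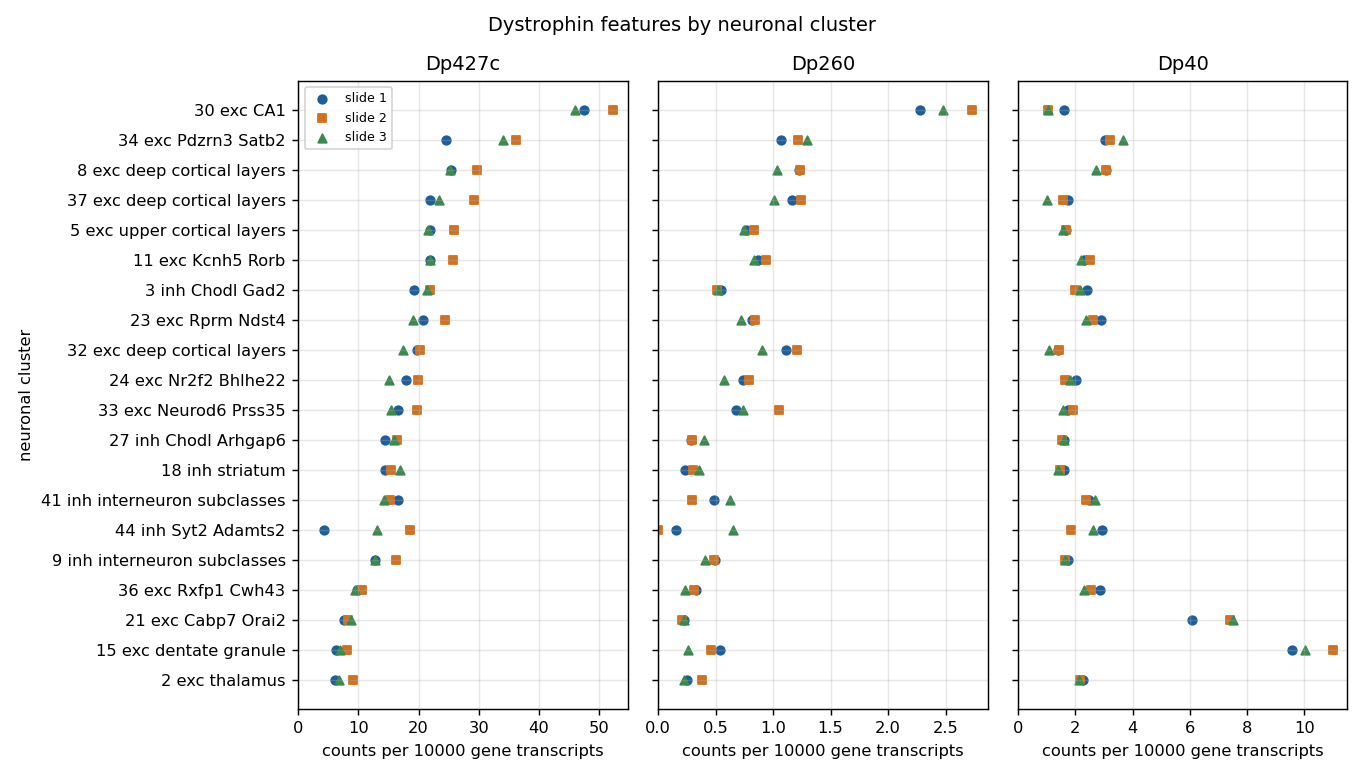
Levels of Dp427c, Dp260 and Dp40 in counts per 10000 gene transcripts in the neuronal clusters, with points for slides 1, 2 and 3. Dp427c is highest in the CA1 cluster (47.5, 52.4 and 45.9) and Dp40 in the dentate granule cluster (9.56, 11.0 and 10.0).

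The other fixed lists, of synapse, activity, immune, peptide, growth factor and vascular genes, were compared between classes in the same way. Of their 43 measured genes, 36 were higher and 40 lower in at least 1 class. Among 9 glial reactivity and immune genes, 7 were higher in microglia or macrophage-like cells. Trem2, a microglial lipid receptor, was 19.9 to 24.3-fold higher there and Cd68, a lysosomal protein of phagocytes, 15.6 to 18.0-fold. The 7 also included the astrocyte gene Gfap, at 695, 453 and 394 there against 378, 234 and 225 in astrocyte-like cells. RNA of astrocytes in microglia or macrophage-like cells was therefore not ruled out. Pglyrp1, a peptidoglycan recognition protein, was 23.1 to 27.04-fold and Slfn5 7.22 to 12.1-fold higher in endothelial-like cells. Of 3 vascular genes, all were higher in endothelial-like cells, with Ly6a at 16.2 to 18.7-fold and Car4, a membrane carbonic anhydrase, at 4.07 to 4.96-fold. Fn1, which encodes fibronectin, led in fibroblast or meningeal-like cells at 8.12 to 9.81-fold.

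Of 9 genes of the list of neuropeptides and of stress and mood receptors, 7 were higher in inhibitory neuron-like cells, 5 neuropeptide genes (Cort, Crh, Nts, Pdyn and Penk) and 2 receptor genes (Npy2r and Tacr1). Npy2r was highest in ependymal or choroid plexus-like cells in slide 1. The 7 included Pdyn, the dynorphin precursor (7.53 to 8.37-fold), Cort, which encodes cortistatin (6.79 to 10.4-fold), Tacr1, the substance P receptor (6.19 to 7.23-fold), and Penk, the enkephalin precursor (5.75 to 6.22-fold). Of 5 activity-regulated genes, 3 were higher in excitatory neuron-like cells. Bdnf, a neurotrophin, was 4.68 to 5.40-fold, Nrn1 4.16 to 4.42-fold and Arc 2.03 to 2.39-fold higher, whereas Fos led there at 1.76 to 1.98-fold without passing the rule. Of 4 excitatory synapse genes, Syndig1 (2.27 to 2.34-fold) and Shisa6, an AMPA receptor partner (2.15 to 2.47-fold), were higher in excitatory neuron-like cells, and Neto2, a kainate receptor partner (2.21 to 2.55-fold), in inhibitory neuron-like cells. Grik3, a kainate receptor subunit, led there at 2.00 to 2.44-fold, just short of the rule in 1 slide. Arc was not called with all genes used for clustering (2.07), with coarser clusters (1.95) or with another subsample (2.03), and Shisa6 not with all genes (1.73) or finer clusters (1.76).

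Of 13 growth factor genes, 7 were higher in fibroblast or meningeal-like cells, 3 in ependymal or choroid plexus-like cells, 2 in excitatory neuron-like cells and 1 each in inhibitory neuron-like, oligodendrocyte precursor-like and microglia or macrophage-like cells. In astrocyte-like, oligodendrocyte-like and endothelial-like cells 0 were higher, and a gene could be higher in more than 1 class. Ccn2, a matrix-associated factor, was 10.7 to 13.0-fold higher in fibroblast or meningeal-like cells. Igf2 was 25.7 to 38.7-fold higher in the same cells and 16.7 to 25.6-fold in ependymal or choroid plexus-like cells, and its leading class differed between slides. Sema3d, a secreted semaphorin, was 9.46 to 12.8-fold higher in oligodendrocyte precursor-like cells, and Igf1 5.10 to 8.86-fold higher in microglia or macrophage-like cells. Pthlh, which encodes a parathyroid hormone-related protein, was 3.84 to 4.44-fold higher in ependymal or choroid plexus-like cells. No gene of the inhibitory synapse list was on the panel. Marker genes of a class were also counted in other classes. Slc17a7, an excitatory neuron gene, reached 37.9% to 41.6% of its excitatory level in endothelial-like cells and 32.2% to 34.3% in astrocyte-like cells. In fibroblast or meningeal-like cells Cldn5 reached 45.9% to 52.0% of its endothelial level and Pdgfra 32.4% to 38.1% of its oligodendrocyte precursor level, and in astrocyte-like cells Cldn5 reached 2.57% to 3.43%; expression of the class itself, RNA of neighbours, mixed cells and misassigned cells were not told apart.

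Between excitatory and inhibitory neuron-like cells, 8 of the 62 list genes were higher, 9 were lower and 45 passed neither bound. Of the 17 dystrophin features, 0 passed either bound. Nrn1 (5.42 to 8.20-fold), Bdnf (4.80 to 6.82-fold), Car4 (3.75 to 4.09-fold), Trbc2 (3.62 to 5.38-fold) and Igfbp6, an insulin-like growth factor binding protein (3.45 to 3.57-fold), were the highest by their smallest slide ratio, and Ccn2 was at 3.19 to 4.39-fold. By their ratio in the slide nearest to 1, the lowest were Tacr1, at 0.0947 to 0.147 times the inhibitory level, Pdyn at 0.135 to 0.163, Cort at 0.106 to 0.168, Pthlh at 0.123 to 0.168 and Penk at 0.159 to 0.201. Nts was also lower, at 0.344, 0.0446 and 0.0635. Trbc2, a T cell receptor gene, was not called with coarser clusters (1.15) or another subsample (2.07), and its level was 2.59, 2.82 and 2.35 in excitatory neuron-like cells.

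Most genes had like levels in the 3 slides. Of 297 genes, 12 differed over 1.5-fold between the highest and lowest slide in all cells, 9 of them highest in slide 1, and 4 over 2-fold. Within classes, 245 pairs of gene and class differed over 1.5-fold and 60 over 2-fold, against 68 and 11 without slide 1, 176 and 42 without slide 2 and 128 and 36 without slide 3. With cells thinned, which also left out cells of few transcripts, 38 differed over 2-fold. Slide 1 was the highest in 17 of 21 such genes over 1.5-fold in astrocyte-like cells, but in 24 of 50 in microglia or macrophage-like, 27 of 61 in ependymal or choroid plexus-like and 8 of 25 in fibroblast or meningeal-like cells, where slide 2 was the highest in 14. The feature for exons 56 to 62 of dystrophin was the most uneven, at 27.1, 7.31 and 7.06 (3.84-fold), while exons 45 to 49 were at 13.9, 14.9 and 13.7 and exon 79 at 20.3, 21.6 and 21.1. Slc6a3, the dopamine transporter, was 3.57-fold higher in slide 1 than in slide 3, Spp1, which encodes osteopontin, 2.34-fold, and Th, the rate-limiting enzyme of dopamine synthesis, 1.98-fold. Ebf3, a transcription factor, was 2.21-fold higher in slide 1 than in slide 2. Within classes, exons 56 to 62 differed 9.87-fold in oligodendrocyte-like cells, Nts, which encodes neurotensin, 7.50-fold in excitatory neuron-like cells, Slc6a3 5.51-fold in oligodendrocyte-like cells, and Dcn, which encodes decorin, 4.16-fold and Spp1 3.89-fold in excitatory neuron-like cells. The make-up of the excitatory class differed by slide, since a cluster led by Nr2f2 held 7501, 2937 and 7382 cells and a thalamus cluster 12868, 17155 and 21789. Without slide 1, 5 genes differed over 1.5-fold and 0 over 2-fold in all cells, against 6 and 3 without slide 2 and 9 and 4 without slide 3; a ratio over fewer slides can only be equal or lower. Sections of different mice or brain levels were not told apart, so these differences carry no group meaning.

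**Figure D4:**
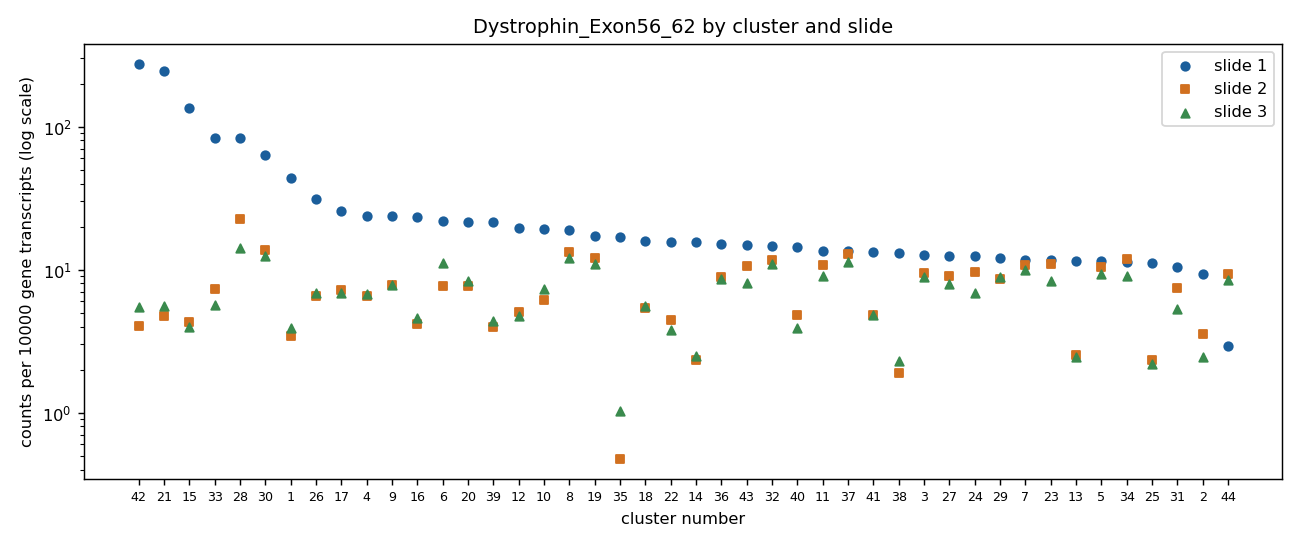
Level of the dystrophin feature for exons 56 to 62 in each cluster, in counts per 10000 gene transcripts on a log scale, with points for slides 1, 2 and 3. In 27 of 44 clusters slide 1 lies at least 2-fold above the mean of the other slides, with at least 20 counts in every slide. Clusters with fewer counts in any slide were not eligible for the 27.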

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

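The tests on dystrophin transcripts in the uneven clusters, on the junction of exons 50 and 53 and on exon block ratios were chosen only after the results were seen; those on stray decoding and on cells of high total were not. No biological explanation that rests on a study group was tested, since no slide has a group.

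Signals outside the gene features rose above every negative control codeword in all 3 slides. DeprecatedCodeword_0334 had 652359, 313110 and 380586 counts, and its level in microglia or macrophage-like cells, the leading class, was 10.7, 11.6 and 11.2-fold over the other named cells. Of the 175 unassigned codewords, 12 passed the same bar. Their counts in the median slide were 5954 for UnassignedCodeword_0073, 3314 for UnassignedCodeword_0028, 2726 for UnassignedCodeword_0093, 2701 for UnassignedCodeword_0016, 2235 for UnassignedCodeword_0322 and 1714 for UnassignedCodeword_0122. The remaining 6 were UnassignedCodeword_0149 with 1471 counts, UnassignedCodeword_0212 with 1443, UnassignedCodeword_0266 with 1227, UnassignedCodeword_0245 with 846, UnassignedCodeword_0409 with 735 and UnassignedCodeword_0053 with 673. UnassignedCodeword_0149 was highest in microglia or macrophage-like cells and UnassignedCodeword_0122 in inhibitory neuron-like cells. Single negative control probes reached 2743, 3009 and 2877 counts. Of the 12 codewords, only UnassignedCodeword_0073 and UnassignedCodeword_0028 were above those in every slide. The bar was the highest of 41 control codewords, and how many of 175 like codewords would pass it was not estimated.

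In 27 of 44 clusters the feature for exons 56 to 62 was at least 2-fold higher in slide 1, with at least 20 counts in every slide. Clusters with fewer counts were not eligible. In slide 1, 5805 cells with 10 or more counts held 46.8% of the counts of the feature, against 2 and 82 such cells in slides 2 and 3. More dystrophin transcripts did not account for the higher level in slide 1, since exons 45 to 49 and exon 79 were at 0.954 times the other slides in the 27 clusters. Stray decoding spread over many codewords was also argued against, with pooled control and unassigned codewords at 1.03 times the other slides. Such a pool cannot show misreading into this feature alone. It also left out DeprecatedCodeword_0334, which had 652359, 313110 and 380586 counts. Without the top 1% of cells by transcripts, slide 1 stayed 3.80-fold higher, so cells of high total did not account for it either. A probe-specific signal in slide 1, misreading into this feature alone and a real change limited to these exons all stay open and were not tested.

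The junction of exons 50 and 53 had counts near the mean negative control probe over all cells. Signal like that of the negative control probes stays undecided. Among the 4 classes with 10% or more of the cells, 19 of 81 pairs of probe and slide were at least as uneven as the junction. By slide these were 5, 11 and 3 of 27 probes, against a highest over lowest class ratio of 3.05, 1.88 and 3.17 for the junction. This count ignores direction. The junction was highest in excitatory neuron-like cells in slides 1 and 3 and in astrocyte-like cells in slide 2. In excitatory neuron-like cells 3, 2 and 0 of the 27 probes were highest, so few probes went the way of the junction in slides 1 and 3. A constant share of the junction of exons 51 and 53 misread as 50 to 53 stays undecided: with the mean negative control probe of the class subtracted, the share was 15.4%, 22.1% and -4.34% in endothelial-like cells and 0.0898%, 4.62% and 1.52% in inhibitory neuron-like cells, and the counting intervals of the 2 classes lay apart in slide 1 only. Excitatory neuron-like cells were at 4.75%, 4.52% and 7.01%, and their intervals lay apart from those of inhibitory neuron-like cells in slides 1 and 3 but not in slide 2. All these intervals vary the 50 to 53 count alone and hold the 51 to 53 count and the subtracted mean fixed. Single negative control probes ranged from 87 to 2743 counts in slide 1. The intervals are therefore too narrow to decide whether shares differ between classes. Misreading, background and skipped transcripts, or a mixture, were not separated, and the same subtraction gave shares below 0 in oligodendrocyte-like and in microglia or macrophage-like cells in every slide and in 5 other classes in some slides.

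Relative to exons 30 to 44, exons 45 to 49 were higher in oligodendrocyte-like cells (2.20 to 2.66-fold) and their precursors (1.73 to 1.91-fold) than in excitatory neuron-like cells, and also in microglia or macrophage-like (1.36 to 1.84-fold), endothelial-like (1.43 to 1.70-fold) and astrocyte-like cells (1.30 to 1.44-fold), and less so in inhibitory neuron-like cells (1.12 to 1.15-fold), but not in ependymal or choroid plexus-like cells (0.784 to 0.854) or in every slide in fibroblast or meningeal-like cells (0.936 to 1.12). RNA from neighbouring neurons alone would leave the ratio near that of neurons. At its lowest in the oligodendrocyte lineage the ratio was 1.73 times the excitatory value of the same slide. It was 1.05 to 1.56 in that lineage against 0.672 to 0.727 in inhibitory neuron-like cells. These values are those that raised the question and are no separate test, and a part from neighbouring neurons was not excluded. Probe background reached at most 1.10% of the level of exons 45 to 49 in the oligodendrocyte lineage and 1.57% in microglia or macrophage-like cells. Transcripts that begin at the Dp140 promoter may contribute, since Dp140 was at least 2.13-fold higher in the precursors, but its 21, 22 and 26 counts there were about those of a mean negative control probe. Dp140 was not called higher in oligodendrocyte-like cells, where the ratio of the exon blocks was highest. A part of such transcripts stays undecided.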

How the results depend on the processing

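Direction was followed for the dystrophin complex list and the 4 named genes of each other list, each in its leading class of slide 1. It was also followed for the named genes and the dystrophin features of excitatory against inhibitory neurons. None of the called results among these turned direction under the alternatives run. Other calls were followed only as counts. The cause of the changes below was not tested. No paired analysis was possible because the results come from no test and no slide has a group. Class shares left the counting interval of their main value as follows, in the median slide. With a minimum of 50 transcripts they were oligodendrocyte 14.9%, ependymal or choroid plexus 1.65%. With all genes clustered they were excitatory neuron 27.2%, inhibitory neuron 12.5%, astrocyte 12.1%, oligodendrocyte 15.5%, oligodendrocyte precursor 2.71%, endothelial 8.68%, fibroblast or meningeal 3.18%, ependymal or choroid plexus 1.75%. At 0.5 times the resolution they were excitatory neuron 26.4%, inhibitory neuron 17.3%, astrocyte 9.40%, oligodendrocyte precursor 3.04%, microglia or macrophage 3.75%, endothelial 9.92%, fibroblast or meningeal 3.15%. At 2 times the resolution they were inhibitory neuron 12.7%, astrocyte 11.0%, oligodendrocyte precursor 3.22%, endothelial 8.33%, fibroblast or meningeal 1.68%, ependymal or choroid plexus 1.58%. With another subsample they were excitatory neuron 28.5%, inhibitory neuron 12.9%, oligodendrocyte 15.6%, microglia or macrophage 4.67%, endothelial 7.79%. Without the 10% of cells of smallest margin they were excitatory neuron 30.9%, astrocyte 9.90%, oligodendrocyte 15.7%, oligodendrocyte precursor 2.87%, microglia or macrophage 4.62%, endothelial 7.74%, fibroblast or meningeal 3.21%, ependymal or choroid plexus 1.85%. Without the top 1% of cells they were excitatory neuron 29.6%, oligodendrocyte 15.4%. Leaving out each slide gave excitatory neuron 29.2% to 30.4%, inhibitory neuron 12.9% to 13.7%, astrocyte 10.51% to 10.8%, oligodendrocyte 15.1% to 15.6%, microglia or macrophage 4.64% to 5.50%, endothelial 7.80% to 8.02%, fibroblast or meningeal 2.88% to 3.26%, ependymal or choroid plexus 1.57% to 2.17%. For single genes, 1152 values kept their side of the rule, 34 newly passed it, 19 no longer passed and 9 uncalled ones crossed 1. Median transcripts per cell were 322 with a minimum of 50. As mean counts per cell, 13 pairs of dystrophin feature and class and 14 members of the dystrophin complex list were higher. By the same measure, the highest over the lowest neuronal cluster was 9.99 for Dp427c and 3.71 for exon 79. For exon 79 it was 3.56 without the cells of smallest margin. With a size rule of 1.5, 16 members of the dystrophin complex list were higher. Under that rule, 13 members of all lists were higher and 14 lower in excitatory than inhibitory neurons. With thinned cells, which also left out 24068, 24783 and 45548 cells with too few transcripts, 38 pairs of gene and class differed over 2-fold between slides, against 60 in the main analysis. Leaving out each slide gave 7 to 11 higher dystrophin pairs, 6.59 to 7.32 for Dp427c, 3.20 to 3.39 for exon 79 and 7.996 to 10.1 for Dp40 highest over lowest neuronal cluster, 5 to 9 genes over 1.5-fold and 0 to 4 over 2-fold between slides in all cells, 68 to 176 pairs over 1.5-fold against 245 and 11 to 42 over 2-fold against 60, and a share of the 50 to 53 junction of 10.9% to 12.9%. The lowest spread counts, 5, 0, 68 and 11, were those without slide 1. With the mean negative control probe subtracted, chosen after seeing the data, that share was 2.78%. Over all cells Dp140 had 0.456, 0.415 and 0.385 times the counts of the mean negative control probe and the 50 to 53 junction 1.11, 1.38 and 1.23 times, which limits what either can show; the effect of greater depth was not tested.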

Other observations

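Among 9 glial reactivity and immune genes, Gfap, Trem2, Cd68, Cd44, Spp1 and Slfn5 were highest in slide 1 over all cells, and Pglyrp1, Cd74 and Trbc2 were not. Gfap, an intermediate filament of reactive astrocytes, was at 204, 133 and 121 counts per 10000 gene transcripts, Trem2 at 42.2, 28.0 and 25.9, Cd68 at 25.5, 17.8 and 17.2 and Cd44, an adhesion receptor, at 9.63, 6.43 and 6.75. Pglyrp1 was at 6.91, 8.45 and 8.51, Cd74, the invariant chain of antigen presentation, at 9.89, 9.78 and 10.1, and Trbc2 at 1.72, 1.78 and 1.68. Levels over all cells also depend on class shares, and that of microglia or macrophage-like cells was 6.21%, 4.79% and 4.49%. Within that class Trem2 was at 407, 332 and 328 (1.24-fold), Cd68 at 218, 180 and 185 (1.21-fold), Spp1 at 171, 70.1 and 65.6 and Igf1 at 68.5, 41.1 and 39.2, and Cd74 was lower in slide 1, at 52.98 against 97.6 and 94.2. Aqp4, an astrocyte gene, was also higher in slide 1 within that class, at 149.8, 100.6 and 102.7 (1.49-fold), so RNA of astrocytes in these cells was not ruled out. The class was made up differently by slide, since cluster 14, led by Cd53, held 13050, 7757 and 6907 of its 20424, 15187 and 14708 cells, and cluster 38, led by Siglech, 1238, 2191 and 2535. Gfap was at 378, 234 and 225 in astrocyte-like cells and at 695, 453 and 394 in microglia or macrophage-like cells, its leading class.

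Exon blocks of dystrophin differed in balance between classes. Exon 79 over exons 2 to 29 was 3.14 to 3.30 times the excitatory neuron value in astrocyte-like cells and 3.02 to 3.44 times in endothelial-like cells. The ratio was also raised in fibroblast or meningeal-like (2.37 to 2.39), oligodendrocyte-like (2.08 to 2.29) and microglia or macrophage-like cells (1.63 to 1.94). It was raised less in oligodendrocyte precursor-like and ependymal or choroid plexus-like cells, and not in every slide in inhibitory neuron-like cells (0.992 to 1.11). The astrocyte marker Ntsr2 reached 31.0% to 33.9% of its astrocyte level in endothelial-like cells. RNA of astrocytes in those cells was therefore not ruled out. Exons 30 to 44 over exons 2 to 29 was 2.02 to 2.37 times the excitatory value in ependymal or choroid plexus-like cells, the class in which Dp260 was highest. A cluster led by Syt2, Adamts2 and Pvalb had 1848 cells in slide 1 and 29 and 99 in slides 2 and 3. It was named inhibitory neuron-like from Pvalb, Calb2, Cntnap4 and Zfp536. Unlike the other clusters of that class, it had neither Gad1 nor Gad2 among its 10 leading genes, so its name is uncertain.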
